A study of Homo sapiens with 12 samples.

How the data were processed

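Gene expression was measured in VCaP, a human prostate cancer cell line that came from a vertebral bone metastasis. Per the labels' protocols, the cells were kept in medium with 2.5% charcoal-stripped serum for 100 h before RNA extraction and carried an siRNA pool for 96 h, either a control pool (siSCR) or a pool against PIAS1 (siPIAS1). Testosterone at 100 nM was present for 16 h or left out. This gives 4 groups of 3 arrays, 12 arrays in all. Biotin-labelled RNA was hybridised to Illumina bead arrays with 47323 probes. The labels number the replicates but do not say that they were separate cultures, so every p-value measures only the spread between these samples.

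Of the deposited values, the scanner intensity of each probe on each array was the starting point. It was deposited without normalization, per the file headers, and held no value below 0. A detection p-value per probe and array was deposited beside it, per the file headers. The authors also deposited a table of normalized log2 values. The submitters' processing notes name lumi, and its version and settings are not given in the sources used here. Set against the scanner signals, each column of the authors' log2 table ranked the probes exactly as that array's own signal did (lowest rank correlation 1). Over 1879 probes brighter than 2000 on every array, its differences between arrays had slopes of 0.958 to 1.02 on the log2 signal ratios, so the scale is log2-like with the direction kept. Its lowest value was 7.22 and the array medians lay between 7.60 and 7.61. Genes were not centred, and the exact transform and normalization stay unknown. This table served only as an alternative.

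The intensities were background-corrected and quantile-normalized with neqc in limma 3.58.1 under R 4.3.3, which takes the background from the detection p-values and adds an offset of 16. Probes were named through the platform annotation, with symbols updated through the gene identifier in the RefSeq table of assembly GCF_000001405.40 (GRCh38.p14). Of the probes, 30113 had 1 gene symbol, 8 had several and 17202 had no gene listed. The gene identifier was in the reference for 30074 of those with 1 symbol. A probe was kept when its detection p was under 0.01 on at least 3 arrays, which held for 17835 probes. Among these, 14068 had 1 gene, 2 had several genes and 3765 had no gene listed. Each gene was represented by its detected probe with the highest mean over the 12 arrays, which left 10710 genes. More than 1 detected probe was available for 2707 of them. No gene is named from a probe with several genes. No coordinates of probes were used, because the files name no genome build. The reference served only for names, for which genes are neighbours and for the genomic span of each gene.

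One limma model with 4 group means was fitted to all 12 arrays, with 8 residual and 5.77 prior degrees of freedom. The comparisons were drawn from it, namely those of testosterone after siSCR, testosterone after siPIAS1, siPIAS1 without testosterone, siPIAS1 with testosterone, and the difference between both testosterone responses (the interaction). The average of both testosterone responses was a further contrast. Its error is independent of the interaction's error in this balanced design only if all groups have the same spread. One array of the siPIAS1 group with testosterone varied more, so the independence is not complete. P-values from limma's moderated test were two-sided and adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1 and was not used. Differences are given in log2 units with the standard error after ±, and levels are given as the mean normalized log2 signal ± SD over 3 arrays. The number of arrays limits the precision. The median standard error of a comparison of 2 groups was 0.126.

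Where the probe of a gene was not detected on every array of the dimmer group, the level there is only a bound. The fold is then given as "at least N-fold", from the mean of the brighter group against the mean of, per array, the higher of the lowest normalized signal among detected probes and the probe's own value. Folds at low signal are also compressed by the offset.

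Before the data were examined, 22 gene lists were written from textbook knowledge, together with the rule for the genes to be named. The rule took, for each comparison, PIAS1, the 10 genes with the largest positive and the 10 with the largest negative log2 difference among those past the threshold whose groups did not overlap and which were detected on all 3 arrays of the brighter group, and up to 4 members of each list with the smallest p. The overlap condition did not apply to the interaction, and symbols starting with LOC were not named. With 3 arrays against 3, chance gives non-overlapping groups in 10% of genes. Lists were tested with camera in limma with the preset correlation of 0.01 and again with the correlation estimated from the data, and adjusted over all 105 tests of 21 lists in 5 comparisons. The basal epithelial list had 1 measured gene and was not tested, and the result of 1 tested list is not reported. Genes past the threshold were counted over all genes and also adjusted over the list alone. The shift of the interaction over testosterone-regulated genes was tested with fry, which asks whether a set's genes move one way on balance, and with camera.

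The steps were tested on simulated signals for 10742 genes with known changes in the siPIAS1 arrays with testosterone. For siPIAS1 against siSCR with testosterone, 41.8% of the genes changed 1.5-fold, 71.9% of those changed 2-fold and 98.4% of those changed 4-fold were recovered, with 9 false calls. For the interaction the recovered shares were 8.96%, 45.3% and 95.3%, with 7 false calls. No gene was called for testosterone after siSCR, where none had been changed. The simulation gave a gene the same spread on every array and changed only a small set of genes. In the data, 1 array of the siPIAS1 group with testosterone varied more and many genes changed, so these shares may not carry over.

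Alternatives covered the authors' values, no background correction, an offset of 50, scaling to the 75th percentile, other filters, every detected probe, the replicate number as a block, array weights, another prior, only the arrays compared, stricter thresholds and leaving out each array. All were fixed with the lists, except leaving out replicate 3 of the siPIAS1 group with testosterone in the list tests, the list tests under other backgrounds, scalings and offsets, and signals under detection raised to the lowest detected signal of their array, which were added after the data were seen. A slide block was not run because the files used here give no slides.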

Results

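The transcriptome of VCaP prostate cancer cells was profiled on 12 arrays to ask how the androgen response depends on PIAS1, a SUMO E3 ligase. Cells carried control siRNA or PIAS1 siRNA and were left without testosterone or given 100 nM for 16 h, with 3 arrays in each of the 4 groups. Between 32.5% and 36.0% of the probes were detected per array, and the median scanner signal lay between 93.7 and 110 per array. No 2 arrays of a group shared identical values. Correlations of normalized signals were 0.978 to 0.996 within groups and 0.901 to 0.986 between groups. The first principal component held 67.0% of the variance and the second 16.3%. One array stood apart. Replicate 3 of the siPIAS1 group with testosterone had a mean correlation of 0.978 with the other arrays of its group, against at least 0.986 for every other array, and an array weight of 0.118. Its genes deviated from the mean of the other arrays of the group with an SD of 0.415, against 0.153 to 0.263 on the other 11 arrays.

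PIAS1 itself, measured by its only detected probe, was lowered by the siRNA in both settings. Its normalized log2 signal was 10.32 ± 0.06 after siSCR and 9.11 ± 0.13 after siPIAS1 (SD, n = 3), a difference of -1.21 ± 0.11 or 2.31-fold (limma adjusted p = 9.00e-06). Testosterone raised PIAS1 by 1.09 ± 0.11 after siSCR (adjusted p = 1.48e-06) and by 1.54 ± 0.11 after siPIAS1 (adjusted p = 3.97e-08). With testosterone the levels were 11.41 ± 0.08 and 10.65 ± 0.16, a 1.7-fold difference (-0.76 ± 0.11, adjusted p = 1.50e-04). The mean PIAS1 signal of siPIAS1 cells with testosterone thus lay above that of siSCR cells without it, a pair of groups that was not tested. The difference between both knockdowns, 0.44 ± 0.15, did not pass (adjusted p = 0.0800).

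**Figure D1:**
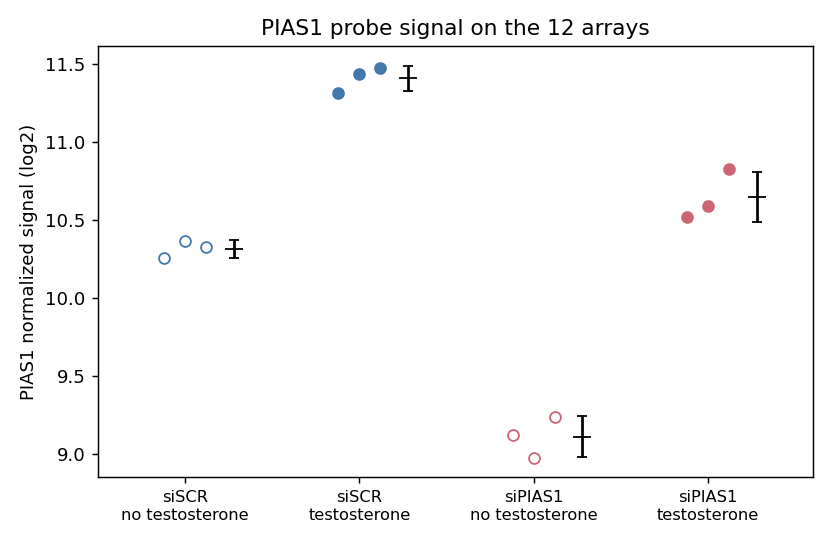
Normalized PIAS1 signal (log2, vertical axis) on each of the 12 arrays by group (horizontal axis), with open circles for arrays without testosterone, filled circles for arrays with it, and a black bar for the mean ± SD of 3 arrays. The siPIAS1 means lie at 9.11 ± 0.13 and 10.65 ± 0.16, below the siSCR means at 10.32 ± 0.06 and 11.41 ± 0.08 for the same testosterone setting.

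The first comparison asked which genes respond to testosterone in control cells. Testosterone changed 4748 of 10710 genes, with 2145 higher and 2603 lower, and 1073 of them changed at least 2-fold. With scaling to the 75th percentile the balance turned, to 2383 higher and 2309 lower. CST1, a secreted cysteine protease inhibitor, rose at least 159-fold, from 4.99 ± 0.04, below detection, to 13.45 ± 0.11 (adjusted p = 9.64e-16). CST4 of the same cystatin family rose at least 16.3-fold (from 5.05 ± 0.10 to 10.16 ± 0.09). FKBP5, an immunophilin, rose 16.1-fold (4.01 ± 0.09), and NCAPD3, a condensin II subunit, rose 19.6-fold (4.30 ± 0.12). The acute-phase orosomucoid ORM2 rose at least 76.3-fold (from 5.96 ± 0.20 to 12.40 ± 0.14) and ORM1 at least 6.46-fold (from 4.84 ± 0.01 to 8.83 ± 0.19). CST1 and CST4, like ORM1 and ORM2, are close copies whose probes may not be separable. Further large increases were those of ADGRG2, an adhesion receptor, at least 35.2-fold (from 5.37 ± 0.15 to 11.27 ± 0.02), EMP1, at least 12.2-fold (from 5.07 ± 0.22 to 9.75 ± 0.06), the metalloreductase STEAP4, at least 8.18-fold (from 4.73 ± 0.11 to 9.17 ± 0.25), and the anion exchanger SLC26A3, at least 6.6-fold (from 4.65 ± 0.05 to 8.86 ± 0.07).

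Among the strongest decreases with testosterone in control cells was that of IGFBP3, an insulin-like growth factor binding protein, at least 25.9-fold, from 10.99 ± 0.12 to 5.86 ± 0.18. CCN3, a matricellular protein, fell at least 14.2-fold (from 10.12 ± 0.04 to 5.31 ± 0.16), and the ligand WNT2 at least 8.75-fold (from 9.42 ± 0.07 to 5.03 ± 0.12). FOLH1, which encodes prostate-specific membrane antigen, fell at least 12.7-fold (from 10.13 ± 0.18 to 6.45 ± 0.11). PPFIA2 fell at least 10.2-fold (from 9.64 ± 0.07 to 4.98 ± 0.13), SLC3A1, an amino acid transporter subunit, at least 13.9-fold (from 10.09 ± 0.02 to 5.57 ± 0.15), and NSG1 16.6-fold (-4.05 ± 0.11). TRIM51 fell at least 22.4-fold (from 10.90 ± 0.15 to 6.37 ± 0.20, detected there on 1 of 3 arrays) and TRIM48 at least 9.01-fold (from 9.47 ± 0.22 to 5.26 ± 0.25), with the caution that TRIM genes of this group have close paralogs. SYTL2 fell 18.8-fold (-4.24 ± 0.12) on its brightest probe, and its other detected probes gave -3.72 and -0.76.

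Known androgen programmes moved as groups. Of 36 androgen-induced genes, 30 rose, 3 fell and 3 did not pass, with 30 and 3 adjusted over the list alone (median 1.06, camera adjusted p = 2.64e-15); SGK1, a kinase, gained 3.26 ± 0.10. Among the members that fell was ADAMTS1, a secreted metalloprotease, at -1.97 ± 0.11. Of 13 androgen-repressed genes, 1 rose, 10 fell and 2 did not pass, with 1 and 10 adjusted over the list alone (median -1.60, adjusted p = 6.58e-06). UGT2B15 and UGT2B17, close paralogs that glucuronidate androgens, fell at least 3.66-fold (from 8.17 ± 0.05 to 4.68 ± 0.11) and 6.21-fold (from 8.93 ± 0.02 to 6.08 ± 0.20), and the opioid receptor gene OPRK1 fell by 3.15. UGT2B11, counted among those that fell, gave -0.68 on its brightest probe and 0.17 on the other. Cell division genes fell together. In the DNA replication list of 27 genes, 0 rose, 23 fell and 4 did not pass, with 0 and 24 adjusted over the list alone (median -1.49, adjusted p = 5.22e-13), among them CDC45 (-2.33 ± 0.10), MCM4 (-2.03 ± 0.10) and PRIM1 (-2.08 ± 0.11). Of 30 mitosis genes, 0 rose, 28 fell and 2 did not pass, with 0 and 29 adjusted over the list alone (median -0.59, adjusted p = 1.13e-07), including KIF11 (-0.92 ± 0.11) and CENPA (-0.90 ± 0.13).

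Lipid synthesis and unfolded protein response genes rose with testosterone in control cells. Of 18 cholesterol genes, 15 rose, 0 fell and 3 did not pass, with 15 and 0 adjusted over the list alone (median 0.65, adjusted p = 6.21e-07), led by IDI1 (1.80 ± 0.10) and NSDHL (1.27 ± 0.11). Of 16 fatty acid synthesis genes, 11 rose, 1 fell and 4 did not pass, with 11 and 1 adjusted over the list alone (median 0.53, adjusted p = 0.00126). ELOVL7 gained 1.41 ± 0.09 and ACLY 1.04 ± 0.10, and FABP5, a fatty acid binding protein, was the member that fell (-1.75 ± 0.14). Of 19 unfolded protein response genes, 16 rose, 0 fell and 3 did not pass, with 16 and 0 adjusted over the list alone (median 0.59, adjusted p = 6.58e-06), with DNAJB9 at 1.62 ± 0.12 and HYOU1 at 0.74 ± 0.09. These calls held with an estimated correlation, with adjusted p between 0.00790 (mitosis) and 0.0238 (fatty acid synthesis). Of 10 NF-kB response genes, 6 rose, 1 fell and 3 did not pass, with 6 and 1 adjusted over the list alone, including TNFAIP3, at least 3.01-fold (from 5.48 ± 0.17 to 7.73 ± 0.06), and the chemokine CCL2, at least 9.04-fold (from 6.15 ± 0.15 to 9.35 ± 0.64); the list passed (adjusted p = 0.0101), and adjusted p = 0.174 with an estimated correlation. Hypoxia and glycolysis genes (9 higher, 3 lower and 5 not passing of 17, with 10 and 3 adjusted over the list alone) passed at adjusted p = 0.0362, and adjusted p = 0.340 with an estimated correlation. That call was lost with scaling to the 75th percentile (adjusted p = 0.0697). Luminal epithelial markers (6 higher, 0 lower and 8 not passing of 14, with 6 and 0 adjusted over the list alone), among them the keratins KRT8 (1.11 ± 0.13) and KRT19 (1.17 ± 0.16), passed at adjusted p = 0.0443, and adjusted p = 0.340 with an estimated correlation. The luminal call was also lost with undetected signals raised to the lowest detected one (adjusted p = 0.0522) and on the authors' values (adjusted p = 0.0629).

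The remaining lists reported did not pass for testosterone in control cells, although single members changed. ERG, whose fusion to the androgen-regulated TMPRSS2 promoter is carried by VCaP, rose (1.46 ± 0.09), while ERG-associated genes had 4 higher, 8 lower and 2 not passing of 14, with 4 and 8 adjusted over the list alone (adjusted p = 0.218). The SUMO pathway had 1 higher, 3 lower and 11 not passing of 15, with 1 and 3 adjusted over the list alone (adjusted p = 0.666), with PIAS1 the member that rose. Polyamine metabolism had 5 higher, 1 lower and 6 not passing of 12, with 5 and 1 adjusted over the list alone (adjusted p = 0.0989), led by ornithine decarboxylase ODC1 (2.12 ± 0.09). Neuroendocrine genes had 1 higher, 7 lower and 2 not passing of 10, with 1 and 8 adjusted over the list alone (adjusted p = 0.0989), p53 targets 6 higher, 4 lower and 6 not passing of 16, with 6 and 4 adjusted over the list alone (adjusted p = 0.586), amino acid response genes 6 higher, 4 lower and 5 not passing of 15, with 6 and 4 adjusted over the list alone (adjusted p = 0.971) and TGF-beta response genes 5 higher, 3 lower and 6 not passing of 14, with 5 and 3 adjusted over the list alone (adjusted p = 0.739). The lists for other cell states held few measured genes. Of 4 mesenchymal genes SNAI2 rose at least 1.94-fold (from 4.63 ± 0.04 to 7.09 ± 0.15), and its other detected probe gave 1.31 in log2 units (list adjusted p = 0.440). Of 3 fibroblast and smooth muscle markers LUM fell at least 3.48-fold (from 8.09 ± 0.15 to 4.91 ± 0.11, list adjusted p = 0.396). Of 3 blood and endothelial markers, 1 was called higher, 1 lower and 1 did not pass (list camera adjusted p = 0.971). CD14 lost signal (-0.65 ± 0.12), and the higher one was LYZ, which was below detection in both groups. DST, the only basal marker measured, was lower, by at least 1.33-fold (from 6.79 ± 0.29 to 6.32 ± 0.14, adjusted p = 0.0172), a call lost on the authors' values (adjusted p = 0.0930) and without any one of siSCR replicates 2 and 3 and siSCR replicate 3 with testosterone (adjusted p up to 0.0817).

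**Figure D2:**
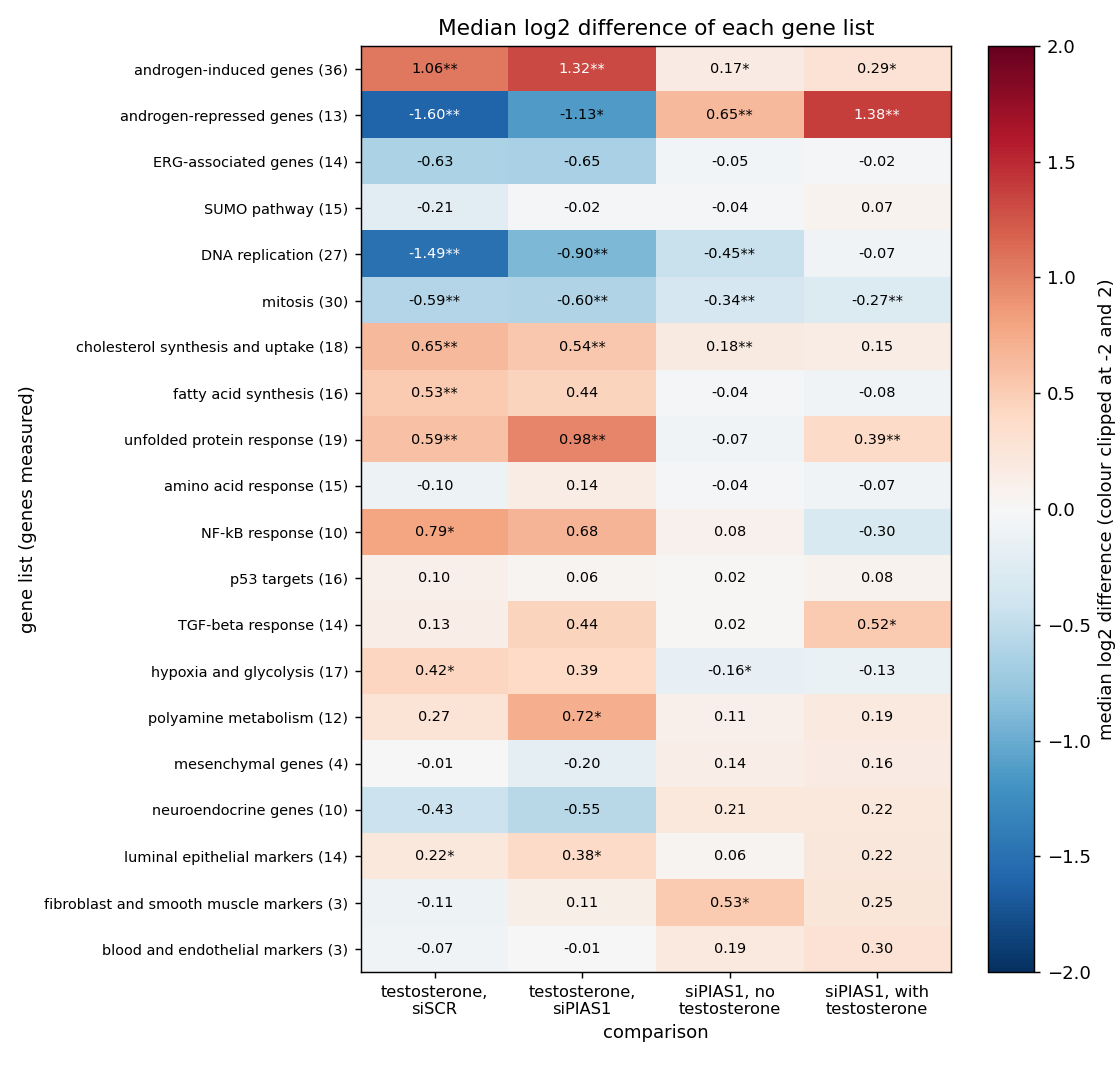
Median log2 difference (colour and number) of the measured genes of each list reported (vertical axis, number of genes in brackets) in the comparisons of 2 groups (horizontal axis), where * marks camera adjusted p under 0.05 with the preset correlation and ** the same also with an estimated one. Androgen-repressed genes have medians of -1.60 and -1.13 with testosterone, and of 0.65 and 1.38 with siPIAS1.

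In cells with PIAS1 siRNA, testosterone changed 5899 genes, 2716 higher and 3183 lower, and 1309 at least 2-fold. The 75th percentile scaling turned this balance too, to 3026 higher and 2632 lower. CST1 again rose at least 156-fold (from 5.00 ± 0.03 to 13.46 ± 0.19), FKBP5 gained 3.98 ± 0.09 and NCAPD3 41.4-fold (5.37 ± 0.12). PGC, which encodes the protease progastricsin, rose at least 26-fold (from 5.06 ± 0.29 to 10.87 ± 0.32), the calcium-binding S100P at least 13.5-fold (from 5.00 ± 0.15 to 9.93 ± 0.13) and the glucose transporter SLC2A3 at least 34.5-fold (from 6.48 ± 0.29 to 11.64 ± 0.13). ENTREP1 rose at least 19-fold (from 5.85 ± 0.21 to 10.42 ± 0.06). PPFIA2 fell at least 22.5-fold (from 10.73 ± 0.12 to 4.90 ± 0.14), IGFBP3 37.4-fold (-5.22 ± 0.12), KCTD12 at least 20.4-fold (from 10.59 ± 0.07 to 5.87 ± 0.07), the junction adhesion gene JAM3 at least 15.1-fold (from 10.23 ± 0.03 to 6.08 ± 0.32) and REEP1 14.1-fold (-3.81 ± 0.13). UGT2B15 fell at least 5.97-fold (from 8.82 ± 0.12 to 4.93 ± 0.10).

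The same gene groups were tested in these cells. Of 36 androgen-induced genes, 31 rose, 2 fell and 3 did not pass, with 31 and 2 adjusted over the list alone (median 1.32, adjusted p = 4.17e-15). Of 13 androgen-repressed genes, 3 rose, 9 fell and 1 did not pass, with 3 and 9 adjusted over the list alone (adjusted p = 0.0244), and adjusted p = 0.0953 with an estimated correlation; UGT2B28 was among those that rose, at least 7.39-fold (from 5.33 ± 0.07 to 9.06 ± 0.13). DNA replication genes fell again (1 higher, 24 lower and 2 not passing of 27, with 1 and 24 adjusted over the list alone, median -0.90, adjusted p = 1.16e-08), as did mitosis genes (0 higher, 24 lower and 6 not passing of 30, with 0 and 24 adjusted over the list alone, median -0.60, adjusted p = 3.49e-05), with MCM4 at -1.55 ± 0.10 and TOP2A at -0.76 ± 0.11. The unfolded protein response list had 17 higher, 0 lower and 2 not passing of 19, with 17 and 0 adjusted over the list alone (median 0.98, adjusted p = 9.86e-09), including DNAJB9 (1.96 ± 0.12) and CRELD2 (1.32 ± 0.10), and the cholesterol list 12 higher, 0 lower and 6 not passing of 18, with 12 and 0 adjusted over the list alone (median 0.54, adjusted p = 2.82e-04). Polyamine genes passed here (6 higher, 2 lower and 4 not passing of 12, with 7 and 2 adjusted over the list alone, adjusted p = 0.0202), and adjusted p = 0.338 with an estimated correlation. Luminal markers passed at adjusted p = 0.0446 (7 higher, 1 lower and 6 not passing of 14, with 7 and 1 adjusted over the list alone), and adjusted p = 0.340 with an estimated correlation. They did not pass on raised signals (adjusted p = 0.0503), on the authors' values (adjusted p = 0.0603) or without the array that stood apart (adjusted p = 0.0553). The androgen-induced, replication, mitosis, cholesterol and unfolded protein calls held with an estimated correlation (adjusted p up to 0.0172). Fatty acid synthesis genes did not pass here (9 higher, 3 lower and 4 not passing of 16, with 9 and 3 adjusted over the list alone, adjusted p = 0.0538), nor did NF-kB response genes (adjusted p = 0.177) or hypoxia and glycolysis genes (adjusted p = 0.0887). The fatty acid list lay near the threshold. It passed on the authors' values, without the array that stood apart, without background correction and with an offset of 50 (adjusted p up to 0.0470). The hypoxia list passed without that array (adjusted p = 0.0393). None of the 3 lists passed in the interaction (adjusted p = 0.394, 0.0706 and 0.898). Calls in all comparisons rest on 1 shared spread per gene, which can raise their overlap above that of independent lists. Both testosterone comparisons share no array. They had 1560 genes higher and 1998 lower in both, where independent lists would share 544 and 774, with 82 genes in opposite directions and a correlation of 0.824 across genes, which are not independent replicates.

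PIAS1 siRNA alone, without testosterone, changed fewer genes than testosterone did. It changed 1428 genes, 810 higher and 618 lower, of which 93 rose and 14 fell at least 2-fold. MS4A8 rose 4.87-fold (2.29 ± 0.10), HEPACAM2 4.62-fold (2.21 ± 0.13), TMEM178A 4.06-fold (2.02 ± 0.12) and COLCA1 3.93-fold (1.98 ± 0.14). ATOH1, a transcription factor of secretory lineages, rose at least 3.54-fold (from 6.24 ± 0.17 to 8.08 ± 0.19), the fatty acid receptor FFAR4 at least 2.7-fold (from 5.49 ± 0.10 to 7.57 ± 0.14) and the matrix protease MMP10 at least 2.67-fold (from 5.55 ± 0.17 to 7.56 ± 0.13). MSMB, a major secreted protein of the prostate, rose at least 1.79-fold (from 5.14 ± 0.12 to 6.98 ± 0.12). The zinc transporter SLC30A2 rose at least 3.22-fold (from 6.14 ± 0.26 to 7.95 ± 0.11); the other detected probes gave 1.15 and 0.55 for MSMB and 0.50 for SLC30A2. Besides PIAS1, the decreases included ACKR3, an atypical chemokine receptor (-1.09 ± 0.10), GPAT3, a glycerolipid synthesis enzyme (-1.11 ± 0.09), KCNK13 (-1.15 ± 0.11), ZNF536 (at least 2.24-fold, from 7.51 ± 0.23 to 6.22 ± 0.29) and SLC25A1, the mitochondrial citrate carrier (-1.07 ± 0.18).

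Androgen-repressed genes rose and cell division genes fell with PIAS1 siRNA alone. Of 13 androgen-repressed genes, 8 rose, 1 fell and 4 did not pass, with 10 and 1 adjusted over the list alone (median 0.65, adjusted p = 1.13e-06), among them the transcription factor HES6 (1.69 ± 0.18), DDC (1.19 ± 0.11) and BCHE (at least 2.01-fold, from 6.17 ± 0.14 to 7.22 ± 0.08). DNA replication genes fell (0 higher, 16 lower and 11 not passing of 27, with 0 and 21 adjusted over the list alone, median -0.45, adjusted p = 1.63e-11), and so did mitosis genes (0 higher, 11 lower and 19 not passing of 30, with 0 and 26 adjusted over the list alone, median -0.34, adjusted p = 8.21e-11), with CDC20 at -0.55 ± 0.11 and MCM4 at -0.49 ± 0.10. The cell cycle inhibitor CDKN1A rose (0.94 ± 0.12), though p53 targets as a list did not pass (adjusted p = 0.312). Cholesterol genes rose (6 higher, 0 lower and 12 not passing of 18, with 7 and 0 adjusted over the list alone, median 0.18, adjusted p = 6.07e-04), with HMGCS1 at 0.80 ± 0.10. These 4 calls held with an estimated correlation. Androgen-induced genes had 13 higher, 2 lower and 21 not passing of 36, with 14 and 2 adjusted over the list alone (median 0.17, adjusted p = 6.65e-04), and adjusted p = 0.280 with an estimated correlation. TSC22D3 of that list gained 0.94 ± 0.12. With testosterone, however, TSC22D3 was lower in these cells, at -0.42 after siSCR and -0.72 after siPIAS1 on its brightest probe. Hypoxia and glycolysis genes had 1 higher, 5 lower and 11 not passing of 17, with 1 and 6 adjusted over the list alone (adjusted p = 0.0297), and adjusted p = 0.340 with an estimated correlation. Of the fibroblast and smooth muscle markers TAGLN (0.83 ± 0.13) and LUM (0.53 ± 0.11) rose and the list passed (adjusted p = 0.0362), and adjusted p = 0.138 with an estimated correlation. It did not pass without siPIAS1 replicate 3 with testosterone (adjusted p = 0.0553). The count of 1428 fell to between 765 and 906 without any one of the 6 arrays compared and was 2481 without siPIAS1 replicate 3 with testosterone, which sets part of the shared spread. It rose to 3357 with array weights and to 2707 with only the arrays compared. With scaling to the 75th percentile the split turned to 620 higher and 818 lower.

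With testosterone present, PIAS1 siRNA changed 3586 genes, 1749 higher and 1837 lower, of which 211 rose and 112 fell at least 2-fold. This near-even balance turned with array weights (2386 higher and 2257 lower), without siSCR replicate 1 with testosterone (1833 and 1793) and without siPIAS1 replicate 3 with testosterone (1818 and 1789). TRIM51 was at least 22.9-fold higher (6.37 ± 0.20 against 10.94 ± 0.36) and TRIM48 at least 9.01-fold higher (5.26 ± 0.25 against 9.46 ± 0.49). The related TRIM49D2, TRIM49D1 and TRIM49C were at least 4.1-fold, 4.65-fold and 3.63-fold higher, with means of 4.76 ± 0.09, 5.08 ± 0.17 and 5.09 ± 0.11 against 8.33 ± 0.18, 8.51 ± 0.12 and 8.15 ± 0.14. These copies are nearly identical, so which of them changed is uncertain. GRM5P1, a pseudogene, was at least 5.72-fold higher (5.14 ± 0.09 against 8.81 ± 0.13). UGT2B28 was at least 6.79-fold higher (5.20 ± 0.26 against 9.06 ± 0.13), LYZ, the gene of lysozyme, at least 6.5-fold (5.31 ± 0.08 against 8.99 ± 0.08), the cilium regulator FOXJ1 at least 4.17-fold (5.19 ± 0.25 against 8.35 ± 0.10) and the prostaglandin receptor PTGER4 10.1-fold (3.34 ± 0.11). Among the decreases were MYC (4.15-fold, -2.05 ± 0.12), the chemokines CCL2 (4.67-fold, -2.22 ± 0.24) and CXCL10 (3.37-fold, -1.75 ± 0.20), the growth factor signalling inhibitor SPRY1 (at least 4.31-fold, 8.50 ± 0.05 against 6.32 ± 0.39), MYOF (2.92-fold, -1.55 ± 0.10) and ST6GAL1 (2.94-fold, -1.56 ± 0.16). Hexokinase HK2 fell 3.16-fold (-1.66 ± 0.14), and its other detected probe gave -0.46.

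Androgen-repressed genes stood higher after siPIAS1 in the presence of testosterone too. Of 13, 7 rose, 0 fell and 6 did not pass, with 8 and 0 adjusted over the list alone (median 1.38, adjusted p = 3.57e-07), including UGT2B11 (2.34 ± 0.15) and UGT2B10 (at least 1.38-fold, 4.74 ± 0.06 against 6.76 ± 0.04), paralogs whose probes may share signal. UGT2B17 was at least 3.54-fold higher on its brightest probe (6.08 ± 0.20 against 8.12 ± 0.16), and another probe differed by 0.16 in log2 units. Unfolded protein response genes rose (11 higher, 0 lower and 8 not passing of 19, with 11 and 0 adjusted over the list alone, median 0.39, adjusted p = 1.13e-04), with MANF at 0.83 ± 0.11 and HSPA5, the chaperone BiP, at 0.48 ± 0.09. Mitosis genes fell (0 higher, 14 lower and 16 not passing of 30, with 0 and 14 adjusted over the list alone, median -0.27, adjusted p = 3.76e-04), with HMMR at -0.84 ± 0.14, whereas the DNA replication list did not pass (3 higher, 6 lower and 18 not passing of 27, with 3 and 7 adjusted over the list alone, adjusted p = 0.374). These 3 calls held with an estimated correlation. Androgen-induced genes had 18 higher, 6 lower and 12 not passing of 36, with 19 and 7 adjusted over the list alone (median 0.29, adjusted p = 5.06e-04), and adjusted p = 0.269 with an estimated correlation, with ADAMTS1 (1.78 ± 0.11), the elongation factor ELL2 (1.73 ± 0.12) and HPGD (1.34 ± 0.10) ahead. ADAMTS1 is a member of the list that fell with testosterone in control cells. TGF-beta response genes had 8 higher, 2 lower and 4 not passing of 14, with 9 and 2 adjusted over the list alone (adjusted p = 0.0211), and adjusted p = 0.268 with an estimated correlation; THBS1 gained 2.12 ± 0.16 and ID3 1.31 ± 0.12. Without replicate 3 of the siPIAS1 group with testosterone, the array that stood apart, 3607 genes were called, 2973 of them also called with it. On that array the median deviation of the lists was largest for neuroendocrine genes (-0.40), hypoxia and glycolysis (-0.23), polyamine metabolism (0.21), amino acid response (0.21), luminal markers (0.16), TGF-beta response (0.15) and DNA replication (-0.15), and the basal marker DST deviated by -0.23. The count was 2380 without siSCR replicate 2 with testosterone and 1981 with only the arrays compared. Under that last setting siPIAS1 alone changed more genes (2707), so the order of both siPIAS1 counts turned. Both siPIAS1 comparisons, which share no array, had 390 genes higher and 345 lower in both (132 and 106 for independent lists) and 87 in opposite directions. Here too the shared spread per gene can raise the overlap.

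The response to testosterone itself differed between siSCR and siPIAS1 for 1065 genes, 523 with a positive and 542 with a negative interaction. The balance turned with scaling to the 75th percentile (559 positive and 459 negative), with array weights (1315 and 1297) and without siSCR replicate 1 with testosterone (706 and 678). Where a level was under detection, the interaction is given with such signals raised to the lowest detected one of their array. TRIM51 and TRIM48 had positive interactions of at least 4.29 and 3.02 (adjusted p = 2.08e-08 and 6.87e-06). TRIM51 fell with testosterone after siSCR and was -0.20 ± 0.16 after siPIAS1 (adjusted p = 0.325). UGT2B28 and LYZ were below detection in both groups without testosterone and after siSCR with it, and rose with testosterone after siPIAS1, at least 7.39-fold and 7.07-fold (from 5.33 ± 0.07 to 9.06 ± 0.13 and from 4.96 ± 0.08 to 8.99 ± 0.08). Their interactions were 2.73 and 2.67 on raised signals (adjusted p = 2.08e-08 and 2.08e-08). PTGER4 (2.89 ± 0.16) rose after siPIAS1 by 2.33 ± 0.11 and stood at -0.56 ± 0.11 after siSCR. For the bicarbonate transporter SLC4A4 the interaction was at least 2.10. It went from 7.70 ± 0.06 to 5.45 ± 0.11, below detection, after siSCR and from 7.07 ± 0.20 to 7.76 ± 0.17 after siPIAS1. Negative interactions included those of CEMIP, a hyaluronan-degrading protein (-2.34 ± 0.18), KCTD12 (-1.93 on raised signals) and RASD1, a Ras-related GTPase (-2.24 ± 0.23). CEMIP and KCTD12 were higher after siPIAS1 without testosterone (1.24 ± 0.13 and 1.68 ± 0.11) and fell by more with it than after siSCR. RASD1 rose by 2.38 ± 0.16 after siSCR and stood at 0.13 ± 0.16 after siPIAS1 (adjusted p = 0.506).

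**Figure D3:**
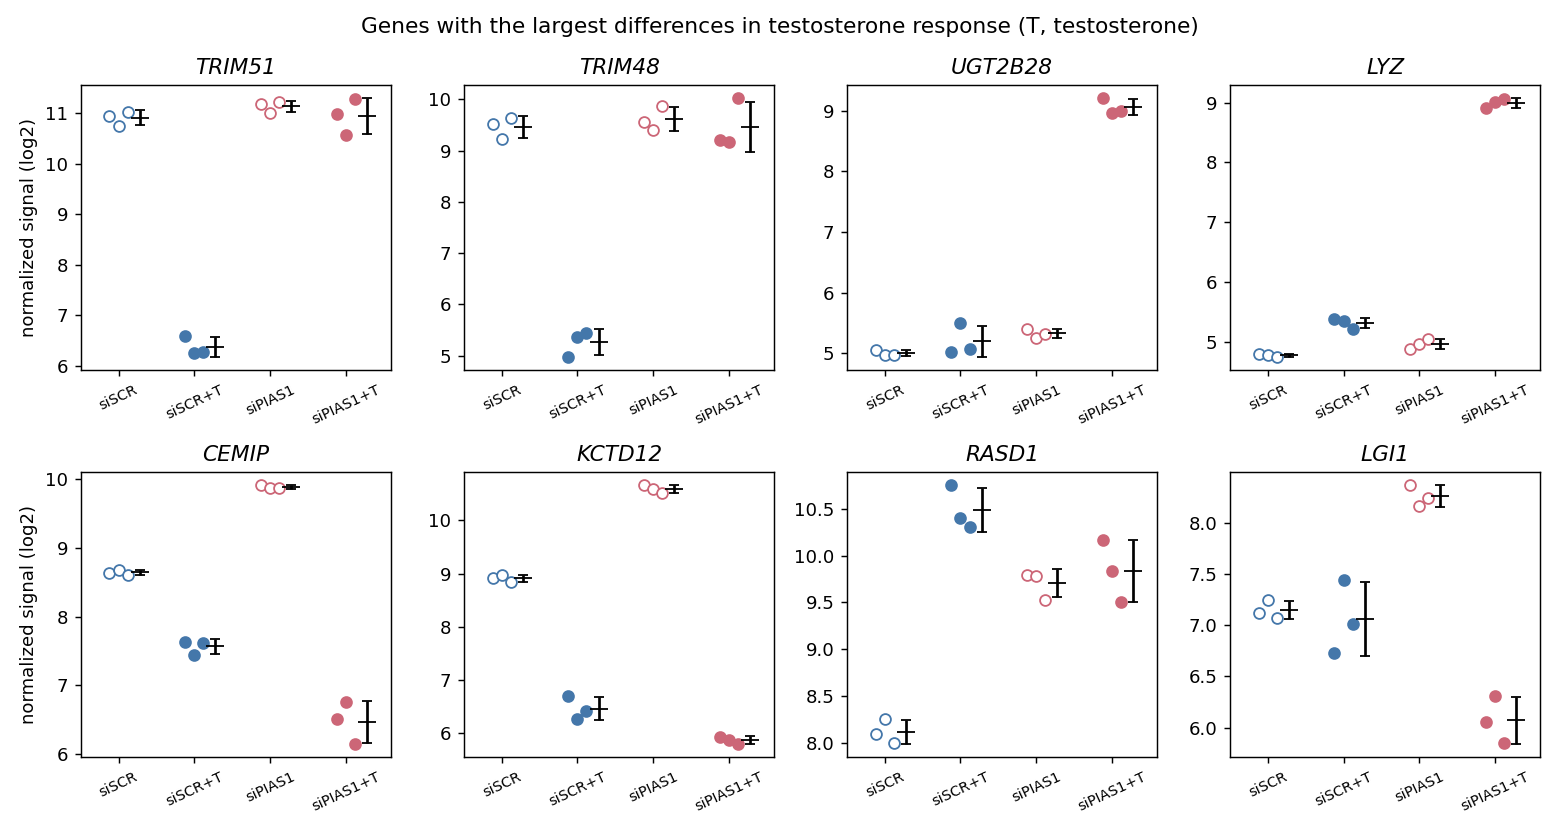
Normalized log2 signal (vertical axes, each on its own range) of the 4 genes with the largest positive and the 4 with the largest negative measured interaction, of which LYZ and UGT2B28 are below detection except after siPIAS1 with testosterone, in the 4 groups (horizontal axes), with 1 circle per array and a black bar for the mean ± SD of 3 arrays. TRIM51 falls to 6.37 ± 0.20 with testosterone after siSCR and stands at 10.94 ± 0.36 after siPIAS1.

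Unfolded protein response genes responded more to testosterone after siPIAS1. In that list, 7 of 19 had a positive interaction that passed and 0 a negative one (8 and 0 adjusted over the list alone), with a median of 0.32 (adjusted p = 1.49e-05, and adjusted p = 0.0141 with an estimated correlation), including SDF2L1 (1.11 ± 0.18) and MANF (0.97 ± 0.15). Androgen-repressed genes had 5 positive and 1 negative of 13 (7 and 2 adjusted over the list alone; median 0.36, adjusted p = 0.00189, and adjusted p = 0.0291 with an estimated correlation), with UGT2B11 at 1.72 ± 0.21 and BCHE at -1.06 on raised signals. The other detected probe of UGT2B11 gave 3.06, and UGT2B17, counted as positive, had an interaction of 1.17 on its brightest probe and -0.68 on the other. The call of the list was lost on the authors' log2 values, where the median was 0.075 (adjusted p = 0.222), and with undetected signals raised to the lowest detected one, where it was 0.28 (adjusted p = 0.0738), while the adjusted p under the other alternatives went up to 0.0291. DNA replication genes fell less with testosterone after siPIAS1, with 6 positive and 0 negative of 27 (10 and 1 adjusted over the list alone; median 0.33, adjusted p = 3.30e-04, and adjusted p = 0.109 with an estimated correlation), such as RRM2 (1.05 ± 0.18) and CDC45 (0.72 ± 0.14). The replication list was already lower after siPIAS1 without testosterone (median -0.45). With testosterone it did not pass between siPIAS1 and siSCR (median -0.07, camera adjusted p = 0.374). TGF-beta response genes passed at adjusted p = 0.0365 (4 positive and 2 negative of 14, 7 and 2 adjusted over the list alone), and adjusted p = 0.310 with an estimated correlation. They did not pass without the array that stood apart (adjusted p = 0.0953) or on the authors' values (adjusted p = 0.0928) or raised signals (adjusted p = 0.0761). The 3 blood and endothelial markers passed at adjusted p = 0.00367, and adjusted p = 0.0944 with an estimated correlation; LYZ passed over all genes, and CD14 (0.50 ± 0.17) adjusted over the list alone, while CD68 stood at 0.05 ± 0.19. Androgen-induced genes had 12 higher, 4 lower and 20 not passing of 36, with 13 and 9 adjusted over the list alone, and did not pass as a list (adjusted p = 0.174; median -0.03, mean 0.20).

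Across all testosterone-regulated genes, the shift of the response was small. Among 3035 genes higher with testosterone on average, the median interaction was 0.086, with 59.6% of genes positive (fry p = 0.0280, camera p = 0.00109, and p = 0.0719 with an estimated correlation). Among 3536 genes lower on average it was -0.10, with 39.1% positive (fry p = 0.0419, camera p = 0.00125, and p = 0.0998 with an estimated correlation). Of the 1065 genes, 434 were higher on average, 439 lower and 192 had no average change. The fry call for higher genes was lost without siSCR replicate 3 and without siSCR replicates 2 and 3 with testosterone (p up to 0.0687). That for lower genes was lost without each of the siSCR arrays in both settings and of siPIAS1 replicates 1 and 3 (p up to 0.122), with scaling to the 75th percentile, where the median was -0.070, and, at -0.10, on raised signals, with the replicate block (p up to 0.0716) and among probes detected on all 12 arrays (p up to 0.0803). The size of the medians depended on single arrays and settings. For lower genes it was -0.054 without siPIAS1 replicate 3 with testosterone and on the authors' values and -0.047 with array weights. For higher genes it was 0.058 without siPIAS1 replicate 3 with testosterone and 0.14 without siPIAS1 replicate 2 with testosterone. Leaving out that replicate 3, which varied most, thus gave the smallest size of both medians among single arrays left out. Its error enters both the choice of the genes and their interaction. The count of 1065 fell to between 656 and 706 without any one of siSCR replicate 3, siSCR replicates 2 and 3 with testosterone, and siPIAS1 replicates 1 and 3.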

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

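The tests on raised signals and those for a mislabelled sample, dimmer hybridisation, a deeper knockdown, one array behind the TRIM genes and a change of their whole neighbourhood were chosen only after the result was seen.

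The response to testosterone was tested for a difference between siSCR and siPIAS1 (the interaction), and 1065 genes differed. Among 100 splits of the arrays within each testosterone setting, 3 gave as many genes, the real split included. The highest other split gave 3542 genes. It exchanges all 3 arrays of both siRNA groups with testosterone and so measures the sum of both siRNA effects, a structure of the samples. The other one gave 1156 genes. It leaves the groups with testosterone whole, exchanges 2 arrays without it and so holds the siPIAS1 effect with testosterone. Since the effect of siPIAS1 itself remains in these splits, they do not decide on chance for the interaction. The count was 668 without siSCR replicate 3, 676 and 656 without siSCR replicates 2 and 3 with testosterone, and 706 and 663 without siPIAS1 replicates 1 and 3.

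The 10 largest positive differences, in log2 units, were TRIM51 4.34, TRIM48 4.06, UGT2B28 3.54, LYZ 3.50, TRIM49D2 3.45, GRM5P1 3.34, TRIM49D1 3.28, SLC4A4 2.94, TRIM49C 2.91 and PTGER4 2.89. The 10 largest negative ones were CEMIP -2.34, KCTD12 -2.27, RASD1 -2.24, LGI1 -2.11, ANXA2P1 -1.94, MMP10 -1.92, FFAR4 -1.91, PTK6 -1.90, ATP1B1 -1.90 and ACSL1 -1.84. These are measured differences, and 9 of the 10 positive and 5 of the 10 negative ones include levels under detection. With such signals raised to the lowest detected one of their array, all 20 kept their sign and their call. The values were then 4.29 for TRIM51, 3.02 for TRIM48, 2.73 for UGT2B28 and 2.67 for LYZ. They were 1.92 for TRIM49D2, 2.18 for GRM5P1, 2.06 for TRIM49D1, 2.10 for SLC4A4 and 1.71 for TRIM49C. The smallest in size was -0.68 for PTK6. ANXA2P1 is a pseudogene, and its probe may share signal with its parent gene ANXA2, as copies of the TRIM group may with each other. Among the TRIM genes listed and GRM5P1, the lowest correlation between 2 genes was 0.861.

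Of the gene lists, 5 differed in their response. With an estimated correlation 3 of them did not pass, namely DNA replication (adjusted p = 0.109), TGF-beta response (adjusted p = 0.310) and blood and endothelial markers (adjusted p = 0.0944). Androgen-repressed genes had a median of 0.36, with UGT2B10 at 1.30, UGT2B11 at 1.72 (3.06 on its other detected probe) and BCHE at -1.09. UGT2B17 of that list turned from 1.17 on its brightest probe to -0.68 on the other. The call of the list was lost on the authors' values (median 0.075, adjusted p = 0.222) and on raised signals (median 0.28, adjusted p = 0.0738). UGT2B10, undetected after siSCR with testosterone, then stood at -0.25 without a call. DNA replication genes had a median of 0.33, with RRM2 at 1.05, MCM5 at 0.91, CDC45 at 0.72 and POLA2 at 0.71. Unfolded protein response genes had a median of 0.32, with SDF2L1 at 1.11, MANF at 0.97, PDIA4 at 0.81 and CRELD2 at 0.66. TGF-beta response genes had a median of 0.40, with THBS1 at 1.49, SMAD6 at 0.96, TGIF1 at -0.75 and ENG at -0.74. They did not pass without siPIAS1 replicate 3 with testosterone (adjusted p = 0.0953), on the authors' values (median 0.14, adjusted p = 0.0928) or on raised signals (median 0.27, adjusted p = 0.0761). SMAD6 lost its call on the authors' values (0.21, adjusted p = 0.104), on raised signals (0.25, adjusted p = 0.293) and without siSCR replicates 2 or 3 with testosterone or siPIAS1 replicate 3 (0.83 to 0.87, adjusted p up to 0.0559). POLA2 lost its call without any one of siSCR replicates 2 and 3, siSCR replicates 2 and 3 with testosterone, siPIAS1 replicates 1 to 3 and siPIAS1 replicate 1 with testosterone (0.60 to 0.74, adjusted p up to 0.0823). The 3 blood and endothelial markers had a median of 0.50.

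Probes with no gene listed carried a signal that no comparison of named genes used. Of 3765 such probes, 1158 changed with testosterone after siSCR, 1641 with testosterone after siPIAS1, 224 with siPIAS1 alone, 912 with siPIAS1 in the presence of testosterone and 1851 with testosterone on average, and 227 differed in their response. Groups of 3 arrays were not tested for outliers.

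Replicate 3 of the siPIAS1 group with testosterone stood apart from the other 2 arrays of its group. A mislabelled sample would sit closer to another group, and its mean correlation was 0.978 with its own group and at most 0.955 with another. The deviations of the array had a correlation of -0.060 with genomic span across genes, within the size of up to 0.225 on the other arrays. Genomic span includes introns and is not transcript length, so this does not decide on uneven RNA integrity. Dimmer hybridisation would lower the share of detected probes, and the array had 35.7% against 32.5% on the lowest other array. GC content could not be tested without probe sequences, the design offers no biological explanation, and a difference in how this sample was handled may underlie it, untested.

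PIAS1 siRNA changed 3586 genes with testosterone (2380 without siSCR replicate 2 of that setting) and 1428 without (765 to 906 without any one of the 6 arrays compared, and 2481 without the array that stood apart, which sets part of the shared spread). With only the arrays compared the order turned, to 1981 genes with testosterone and 2707 without. The counts alone therefore do not settle in which setting siPIAS1 changed more. The ratio of the spread of siPIAS1 effects across genes, with over without testosterone, was 1.60 on all arrays. The measurement error removed from it was pooled over the groups, so extra spread of the array that stood apart stays in this value. Without that array the ratio was 1.44, the lowest without any one array, which argues against that array as the cause. A deeper knockdown with testosterone would give PIAS1 a negative interaction, and it was 0.44 ± 0.15. The 10 splits of the 6 arrays of either comparison are too few for a share under 0.05, with 1 split, the real one, giving as many genes in each, and the highest other split giving 0 genes with testosterone and 2 without. A larger part for PIAS1 when testosterone is present may be a biological explanation, and it stays a hypothesis.

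TRIM48, TRIM51, TRIM49C, TRIM49D1, TRIM49D2 and GRM5P1 fell with testosterone after siSCR and after siPIAS1 they fell less, stayed near their level or stood higher. The lowest interaction of the 6 genes was 2.85 without the array that stood apart and at least 2.81 without any one array, and 1.71 with undetected signals raised, which argues against a single array. The genes lie in 2 groups of neighbours in the reference. Of these neighbours, 4 genes had a median interaction of 0.35, below the 6 genes. The highest was 0.72 (FOLH1, limma adjusted p = 0.0203), whose level after siSCR with testosterone was only a bound. These values argue against a change of that size over the whole neighbourhood. All 4 neighbours fell with testosterone after siSCR (-3.68 to -1.17), and a smaller shared part is not excluded. Among these neighbours was TRIM49, itself a TRIM gene, at 0.44 ± 0.17 (limma adjusted p = 0.125). Separate changes of the TRIM genes and probes shared between near-identical copies cannot be told apart. Without probe sequences, the lowest correlation of 0.861 between 2 of the 6 genes does not decide it. GRM5P1 is a pseudogene and not a TRIM gene, so it is not among these copies. An off-target effect of the siRNA pool was not tested, and a PIAS1-dependent repression of these genes by androgen may be a biological explanation.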

How the results depend on the processing

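The tests of gene lists without siPIAS1 replicate 3 with testosterone and under other backgrounds, scalings and offsets, and every test with undetected signals raised to the lowest detected one of their array, were chosen only after the result was seen.

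With undetected signals raised, 2 called values, which rest on undetected levels, changed sign and lost their call. The interaction of UGT2B10 went to -0.25 and the difference of DNAJC3 with siPIAS1 alone to 0.035. No other called result of a named gene or list changed its direction under the alternatives run for it. For named genes these were the other backgrounds, scalings and offsets, the replicate block and leaving out each array. Named genes other than PIAS1, and the lists, were not run with other filters, array weights, another prior or only the arrays compared. Between detected probes of the named genes 3 called values turned, from the brightest probe to another, and the cause was not tested. They were the interaction of UGT2B17 (1.17 to -0.68), UGT2B11 with testosterone after siSCR (-0.68 to 0.17) and SOD2 with siPIAS1 and testosterone (-0.31 to 0.20). Counts moved by more than 1.5 times as follows, and the cause was not tested unless stated. With every detected probe, where more features are tested, 9155 changed with testosterone after siPIAS1 and 10254 on average. With array weights, 3357 genes changed with siPIAS1 alone and 2612 differed in their response. With only the arrays compared, 2707 changed with siPIAS1 alone and 1981 with siPIAS1 and testosterone, the reverse of the main order. At an adjusted p under 0.01 the siPIAS1 counts were 593 without and 1940 with testosterone, and 422 genes differed in their response. Requiring 1.5-fold left 2621 and 3240 genes with testosterone after siSCR and siPIAS1, 2695 on average, and 527 and 1457 with siPIAS1 without and with testosterone. These stricter thresholds lower counts by construction.

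Scaling to the 75th percentile turned the split of siPIAS1 alone from 810 higher and 618 lower to 620 higher and 818 lower. It also turned the balance for testosterone after siSCR (2145 and 2603 to 2383 and 2309), after siPIAS1 (2716 and 3183 to 3026 and 2632) and on average (3035 and 3536 to 3393 and 3026), and for the interaction (523 and 542 to 559 and 459). Array weights and leaving out siSCR replicate 1 with testosterone turned the near-even balance of siPIAS1 with testosterone and of the interaction, and leaving out siPIAS1 replicate 3 with testosterone the former. The counts include genes below detection in both groups compared, such as LYZ with testosterone after siSCR. On raised signals they were 4520, 5722, 1499 and 3365 for the 4 comparisons and 1164 for the interaction. With the replicate block the counts were 4664, 5816, 1298 and 3410 for the 4 comparisons and 942 for the interaction. Arrays of the same replicate number showed no clear pairing, with correlations of -0.26 to 0.19, of which 3 of 18 exceeded 0.1. This does not exclude that they were handled in pairs, which the labels do not state.

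The median interaction of genes lower with testosterone was no longer past the threshold under the 75th percentile (-0.070), among probes detected on all 12 arrays (-0.10), on raised signals (-0.10) and with the replicate block (-0.10), with fry p-values of 0.397, 0.0803, 0.0716 and 0.0583, and the cause was not tested.

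Leaving out each array gave 4039 to 5767 genes with testosterone after siSCR, 5154 to 5962 after siPIAS1 and 6135 to 7019 on average. With siPIAS1 alone it gave 765 to 2481, namely 765, 782 and 906 without siSCR replicates 1, 2 and 3, 808, 873 and 857 without siPIAS1 replicates 1, 2 and 3, and 2481 without siPIAS1 replicate 3 with testosterone. With siPIAS1 and testosterone it gave 2380 (without siSCR replicate 2 with testosterone) to 3753. In the interaction it gave 656 to 1506, with 668 without siSCR replicate 3, 676 and 656 without siSCR replicates 2 and 3 with testosterone, and 706 and 663 without siPIAS1 replicates 1 and 3. The median interaction ranged from 0.058 to 0.14 for genes higher on average (p up to 0.0687) and from -0.14 to -0.054 for lower ones (p up to 0.122). PIAS1 fell past the threshold without any one array, at -1.27 to -1.14 without and -0.85 to -0.70 with testosterone. A group left with 2 arrays is assumed to vary like the others.

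Of 35 gene list tests past the threshold, 21 passed with an estimated correlation. Over the alternatives that were run for the 105 list tests, 809 values kept their side of the threshold, 26 lost a call and 5 gained one. For 495 results of named genes the numbers were 8625, 213 and 70, besides the 2 that changed sign. Signals near background limit the smallest folds, which the offset compresses. A slide block was not run, since no slides are given.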

Other observations

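The tests of gene families below were chosen only after the result was seen, while the test of a shared effect of siPIAS1 and testosterone and the splits of the arrays were written first.

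The families were picked from the data, so their adjusted p-values are no independent evidence. Of 31 vesicle coat and SEC genes of the early secretory pathway, 22 rose and 1 fell with testosterone after siSCR (median 0.52, camera adjusted p = 5.99e-06, and adjusted p = 0.0299 with an estimated correlation). After siPIAS1, 19 rose and 3 fell (median 0.57, adjusted p = 5.51e-05, and adjusted p = 0.0324 with an estimated correlation). The histone family mixes several types, and probes may not separate close copies within a type. Of 41 histone genes, 22 were higher and 3 lower with siPIAS1 in the presence of testosterone (median 0.45, camera adjusted p = 1.10e-05, and adjusted p = 0.208 with an estimated correlation). All 5 metallothionein genes measured were higher in that comparison (median 0.82, adjusted p = 0.00168, and adjusted p = 0.291 with an estimated correlation). Cytosolic ribosomal protein genes were lower with testosterone after siPIAS1 in 37 of 71 cases (median -0.36, adjusted p = 0.00434, and adjusted p = 0.419 with an estimated correlation).

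PIAS1 siRNA alone lowered replication and mitosis genes, as testosterone did, and siPIAS1 might act on the transcriptome as testosterone does. Across genes, the average siPIAS1 and average testosterone effects had a correlation of 0.0999, and at most 0.138 without any one array. A shared direction for most genes would need a larger value, but the range without single arrays does not exclude a small shared part, so this stays open. Androgen-repressed genes moved the other way, with a median of 0.65 with siPIAS1 alone and -1.60 with testosterone after siSCR.

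For testosterone after siSCR and after siPIAS1, 1 of 10 splits of the 6 arrays, the real one, gave as many genes (4748 and 5899), and the highest other split gave 0. These splits are too few for a share under 0.05. For testosterone on average, 1 of 100 splits, the real one, gave as many as 6571 genes, and the highest other gave 2499. This makes a random division of these arrays an unlikely cause of the count. It cannot speak on differences between cultures, since the labels do not say that the replicates were separate ones. For the median interaction of genes higher on average (0.086), 18 of 100 splits gave a size as large and the highest other was 0.141. For genes lower on average (-0.10), 2 of 100 did, with a highest other size of 0.103. Both counts come from splits of the siRNA groups, in which the effect of siPIAS1 itself remains, so they do not decide on chance. The fry call for lower genes was lost without each of siSCR replicates 1 to 3, siSCR replicates 1 to 3 with testosterone and siPIAS1 replicates 1 and 3 (p up to 0.122).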
